A study of Homo sapiens with 6 samples.

How the data were processed

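CUT&Tag peak lists of 5 libraries from SK-N-BE(2) cells were analysed: HAND2 replicates 1 and 2, MEIS2 replicates 1 and 2, and TCF4. A sixth sample, the IgG control, has no peak list here. Groups were taken from the antibody named in each sample's labels and replicate numbers from the sample titles. Per the submitters' processing notes, the tools were bcl2fastq 2.17, Bowtie2 (version not given in the sources used here) and MACS3 3.0.0a6, with the hg38 build. Options of the aligner and peak caller, duplicate removal and any list of excluded regions are not given in the sources used here. Peaks were called per sample and not on pooled replicates, as the deposited files show.

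Each deposited list gives, per peak, its position, an integer score, the fold enrichment at the summit, and −log10 p and −log10 q, as the authors' peak caller wrote them. The deposited score was 10 times the −log10 q as a whole number, apart from rounding, and was not used. The lowest −log10 q in the deposited lists was 2.00 to 2.02. The deposited fold, a ratio of the summit pile-up to the local background, was used to describe and rank peaks within a list, never to compare levels between lists. In 3 lists the authors added a column equal to the fold divided by peak width, which was not used. No list gave an interval more than once. Peaks outside chromosomes 1 to 22 and X were left out (0, 0, 3, 5 and 7 in the order above). Coordinates are 1-based.

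Depth was read from the lists, which hold no read totals. For each peak the whole pile-up was found whose fold and Poisson p both matched the deposited values within a relative tolerance of 5e-05. It was found for 98.8% of MEIS2 replicate 1 peaks and 100% in the other lists. Tested on 4980 simulated peaks, all pile-ups came back (100%), and 0% did where fold and p came from no whole pile-up. The background unit, 1 IgG fragment after scaling, gave each library's depth relative to IgG. The local background of a peak divided by this unit is called its IgG fragments at the summit. It is a background level and not a direct count of fragments. Above the lowest background of a list, 45.0 to 74.6% of peaks gave a whole number within 0.03. No peak can fall below that lowest background, so peaks there may have fewer fragments than stated. The density of IgG fragments came to 5.64 to 5.65 per kb from every list, and at summits that a pair of lists placed at the same base the log backgrounds correlated across peaks at r = 0.9966 to 1.0000. Pairs with MEIS2 replicate 2 had only 11 to 34 such summits. On these values all 5 lists, TCF4 included, were treated as called against the same control. Counting intervals on folds are exact 95% Poisson intervals of the pile-up with the background held fixed. Fragments are not known to be independent molecules, so all intervals cover counting error only. Identical intervals between replicates numbered 112 for HAND2 and 1 for MEIS2, so no list was a copy of another.

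HAND2 and MEIS2 regions were the merged spans that held a peak of both replicates, with an overlap of at least 1 bp. TCF4 peaks were used as they are. A region's fold in a replicate is the highest of that replicate's peaks within it, and its summit is that of the strongest peak, so either can lie away from a gene end that the region reaches. Overlaps were set beside 100 shuffles within chromosomes (stretches of 1 Mb or more with no gene or peak were left out, as no file of assembly gaps was used) and, added after the data were seen, beside regions moved by 25 to 100 kb. Shares have exact binomial intervals. Regions are not replicates, so these tests describe the lists.

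Gene positions came from the RefSeq gene table of GRCh38.p14, which is the build of the files and gives the start and end of each of 19970 protein-coding genes but no strand, exons or transcripts. The promoter planned before the data were examined (1 kb around the 5′ end) was therefore replaced by 1 kb around either end, and windows of 50 kb were likewise set around both ends. Shares of regions at gene ends count summits within 1 kb of an end. A gene counts as occupied where a region overlaps the 1 kb around an end, and regions within 50 kb are counted by their summits. Exons, introns and UTRs are not given for the same reason. No genome sequence was used, so the planned motif analysis was not run, and random lists were matched on gene length and on the number of genes within 500 kb (5 classes each) in place of promoter GC. GC content therefore stays unmatched in every list comparison.

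The 13 gene lists, fixed before the data were examined, were adrenergic regulators, mesenchymal state, catecholamine synthesis and storage, neuronal differentiation, bHLH and ID factors, TALE homeobox, HOX, neural crest and Schwann cell precursor, cell cycle and DNA replication, ribosomal protein, liver, blood cell and olfactory receptor. Some genes stand in several lists. Occupancy of gene ends was compared with all other protein-coding genes by two-sided Fisher's exact tests. Regions within 50 kb were compared with 10000 matched random lists by a two-sided permutation test. Benjamini-Hochberg adjustment covered the 39 tests of each kind, with a threshold of 0.05. Differences between factors were tested on equal numbers of regions, the 2311 of highest fold for each factor, as the excess over the difference in matched random lists. HOX and olfactory receptor genes lie in clusters and share windows, so their p-values are too small. In simulated lists of 25 independent genes with 70 percent occupancy against 30 percent, 98.5% had an unadjusted Fisher p under 0.05, and 2.5% had with no difference. No adjustment was made there, and no factor had that base share (19.1% of genes for HAND2, 0.946% for MEIS2, 53.9% for TCF4). The simulation therefore gives no power or error rate for the calls below.

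The genes named were set by a rule fixed before the data were examined: HAND2, MEIS2, TCF4 and MYCN in every library, the 10 gene ends of highest fold per factor (lower replicate), the 10 regions of all 3 factors with the best worst rank, the 5 strongest exclusive regions per factor, and for each list the members with the highest folds or most regions. Some genes that the rule names are not reported here. Alternatives tried were a reciprocal overlap of 50%, summits within 200 bp, peaks with −log10 q of 5 or more, the 5000 peaks of highest −log10 q per library, each replicate left out, gene-end windows of 500 bp and 2.5 kb, matched random lists in place of Fisher's test, and windows of 20 and 100 kb. Added after the data were seen were a set without peaks of 30 or more IgG fragments, the replicate number as a block for the gene-end shares of the HAND2 and MEIS2 libraries, and all regions of each factor for the differences between factors. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.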

Results

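The series mapped where 3 transcription factors, HAND2, MEIS2 and TCF4, sit on the genome of SK-N-BE(2), an established human neuroblastoma cell line that carries amplified MYCN. HAND2 is a basic helix-loop-helix (bHLH) factor of the sympathetic lineage, TCF4 an E protein that pairs with other bHLH factors, and MEIS2 a homeodomain factor of the TALE class. The assay was CUT&Tag, in which an antibody tethers a transposase that cuts and tags the DNA near the bound protein. HAND2 and MEIS2 had 2 libraries each and TCF4 had 1, so no TCF4 value has a replicate check. A further library with a non-specific IgG antibody served as control and has no peak list here. Nothing in the labels says that replicates came from separate cultures, so the spread between them may be technical. The lists held 30410 and 33484 peaks for HAND2 replicates 1 and 2, 9595 and 13871 for MEIS2 replicates 1 and 2, and 30704 for TCF4. The median fragment pile-up at peak summits was 34 and 41 for HAND2, 22 and 13 for MEIS2, and 60 for TCF4. Depth relative to the IgG library, read from the background in each list, was 0.789 and 0.932 for HAND2, 0.248 and 0.368 for MEIS2, and 0.784 for TCF4. The MEIS2 lists are thus the shallowest, so a site absent from them is not shown to be free of MEIS2.

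Peaks of the HAND2 libraries recurred at the same places, and those of the MEIS2 libraries mostly did not. Of HAND2 replicate 1 peaks, 78.5% overlapped a replicate 2 peak by at least 1 bp (95% exact binomial interval 78.0 to 79.0%), and 71.6% of replicate 2 peaks overlapped replicate 1. This gave 23304 HAND2 regions present in both replicates, against a mean of 802 when the replicate 2 peaks were shuffled within chromosomes, and a highest value of 850 in 100 shuffles. For MEIS2, 24.6% of replicate 1 peaks (23.7 to 25.5%) overlapped replicate 2, and 16.8% of replicate 2 peaks overlapped replicate 1. The 2311 MEIS2 regions found in both libraries compare with a mean of 79.2 and a highest value of 106 after shuffling. MEIS2 replicate 1 overlapped both HAND2 libraries, at 80.8 and 81.5% of its peaks, more often than it overlapped MEIS2 replicate 2. MEIS2 replicate 2 overlapped the HAND2 libraries at 33.8 and 27.7% of its peaks and TCF4 at 9.01%, whereas 66.6% of MEIS2 replicate 1 peaks overlapped TCF4. The HAND2 and TCF4 lists are longer than that of MEIS2 replicate 2. Shuffled MEIS2 replicate 1 peaks overlapped HAND2 at 2.25 and 2.49%, TCF4 at 2.78% and MEIS2 replicate 2 at 0.844%. The shares therefore do not rank the libraries by overlap relative to chance. All 13876 peak identifiers of MEIS2 replicate 2 carry the word Flag, and none of replicate 1 do, although the labels give the same MEIS2 antibody for both.

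**Figure D1:**
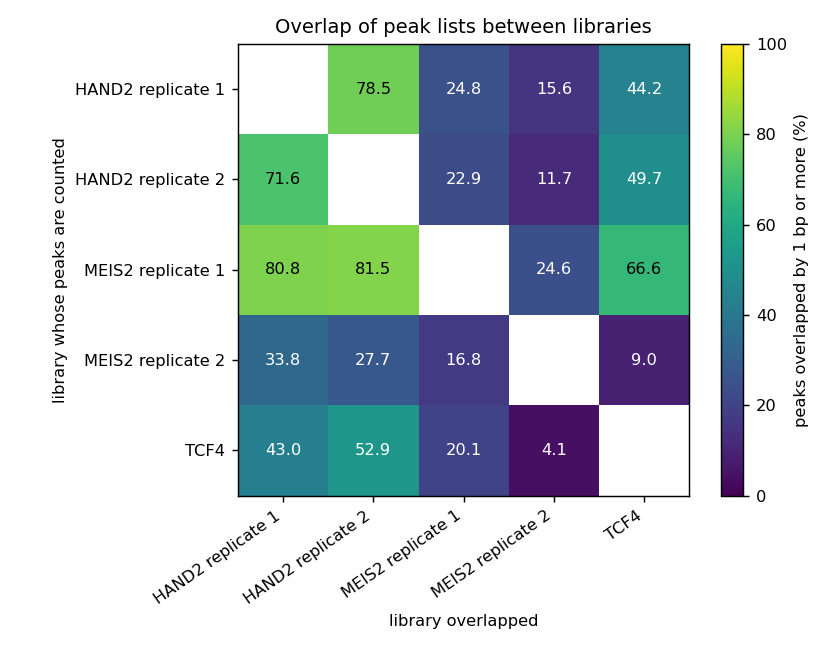
Each cell gives the percentage of the row library's peaks that overlap a peak of the column library by 1 bp or more, for the 5 libraries. The HAND2 replicates share 78.5 and 71.6% of their peaks, and MEIS2 replicate 1 shares more peaks with HAND2 and TCF4 than with MEIS2 replicate 2. The percentages are not adjusted for the length of the column library's list.

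The genes of HAND2 and MEIS2 were themselves occupied by all 3 factors. HAND2 lies on chromosome 4 from 173526091 to 173530229 in GRCh38. Peaks at its ends had a fold enrichment over the local background of 3.85 (95% counting interval 2.26 to 6.19) and 5.01 (3.47 to 7.01) in HAND2 replicates 1 and 2, 20.1 (15.2 to 26.1) and 3.74 (2.03 to 6.45) in MEIS2 replicates 1 and 2, and 12.8 (10.1 to 16.1) for TCF4. In HAND2 replicates 1 and 2, 15 and 11 peaks had their summit within 50 kb of its ends. MEIS2, on chromosome 15 from 36889204 to 37101311, had folds at its ends of 4.88 and 6.44 for HAND2, 17.8 and 2.97 for MEIS2 and 9.85 for TCF4. In MEIS2 replicate 2 that peak lay at the lower-coordinate end of the gene, and in the other 4 libraries at the higher-coordinate end. The MEIS2 replicate 2 peaks at HAND2 and MEIS2 were weak, with pile-ups of 11 and 14. Their −log10 q of 2.88 and 2.23 stood near the lowest of the lists, and the fold at MEIS2 had an interval of 1.72 to 4.86. TCF4 (chromosome 18, 55222185 to 55635957) carried a peak at an end in MEIS2 replicate 2 alone, at 3.97-fold, while 10 and 10 HAND2 peaks, 6 and 10 MEIS2 peaks and 4 TCF4 peaks overlapped its gene body. At MYCN (chromosome 2, 15940550 to 15947004) folds were 1.94 and 1.89 for HAND2, 2.95 in MEIS2 replicate 1 and 4.13 for TCF4, with no peak in MEIS2 replicate 2. Those folds rest on 2462 to 2641 IgG fragments at the summit, against a median of 7 to 14 at the peaks of these 4 libraries. Fold values are the authors', and the intervals cover counting error only.

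**Figure D2:**
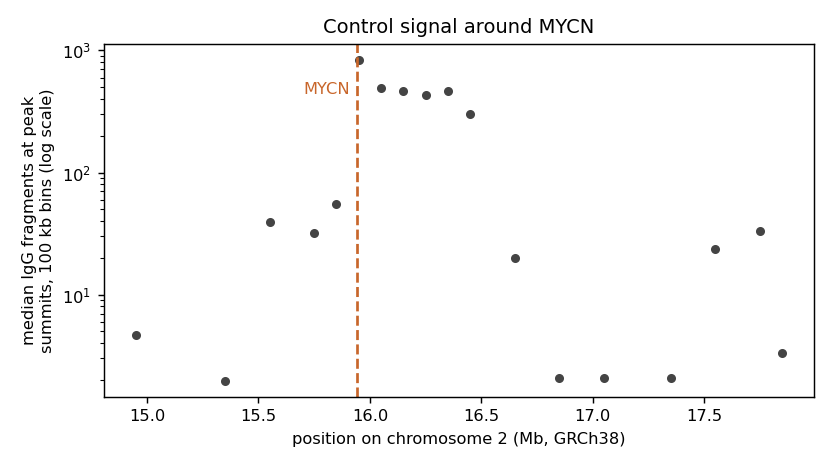
Points give the median background, in IgG fragments, at peak summits of all 5 lists in 100 kb bins of chromosome 2, on a log scale. MYCN is marked by the dashed line, and bins without a peak have no point. Medians lie between 302 and 834.5 from 15900001 to 16500000 and fall to 20 in the next bin with peaks.

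The strongest HAND2 region at a gene end lay at SLC6A2, the noradrenaline transporter gene (chromosome 16, 55655988 to 55706192), with folds of 77.1 (73.1 to 81.2) and 95.5 (91.2 to 99.9) in the HAND2 replicates. Its region ran from 55650040 to 55665695, with the summit 3491 bp from the gene's end. These are the highest folds of each replicate within the merged region, and the replicate 2 peak that reached the gene end of SLC6A2 itself had 27.3. HHIPL2 followed at 56.2 and 61.7, HMCN2 at 55.5 and 56.1, CLDN20, a claudin gene, at 51.6 and 61.5, MB, the myoglobin gene, at 49.0 and 44.0, and POPDC2 at 48.7 and 42.5. CCDC102A, CEP83, STPG4 and STC2, which encodes a stanniocalcin, completed the 10 genes with lower folds of 36.0 to 41.8. MEIS2 regions were present at 7 of these 10 places and TCF4 peaks at 8. At HMCN2 the summit lay 12129 bp from the end that the region touched, and the replicate 1 peak that reached this end had 5.34. At CEP83 no replicate 2 peak of the region reached the end. Gene ends are given without 5′ or 3′, since the gene table used holds no strand.

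MEIS2 was highest at an end of STAU2, an RNA-binding protein gene on chromosome 8 (73420369 to 73747480), with folds of 21.6 (15.4 to 29.4) and 22.4 (16.6 to 29.5). CDC6, which licenses DNA replication origins, had 14.3 (9.39 to 21.1) and 21.4 (15.7 to 28.6), and the neighbouring RARA, the retinoic acid receptor alpha gene, had 15.9 and 13.8. HNMT, which encodes histamine N-methyltransferase, had 10.9 and 21.0, and OLFML3 had 13.1 and 10.3. POPDC2 and MB, also among the highest HAND2 genes, had 34.8 and 11.03, and 39.6 and 10.4. The replicate 1 peak that reached the end of RARA had 6.07, and no replicate 2 peak of the region reached the end of MB. H2AC14 and H2BC14, histone genes that share a region, had 11.2 and 11.3, and H3C6 had 11.2 and 10.2. These histone values are uncertain because the genes have near-identical copies. HAND2 regions overlapped 9 of these 10 places, all but H3C6, and TCF4 peaks overlapped 5.

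TCF4 reached its highest fold at a gene end at LARS2, the mitochondrial leucyl-tRNA synthetase gene (chromosome 3, 45388576 to 45549407), with 145 (134 to 157). A region that overlapped SHF and reached an end of DUOX1, a dual oxidase gene, had 78.1 (75.1 to 81.1), TMEM191B had 75.7, and a region shared by JMJD7, JMJD7-PLA2G4B and MAPKBP1 had 63.2. TMEM191B has a near-identical copy and its value is uncertain. PLAUR, the urokinase receptor gene, had 59.2, IGFBP4, an insulin-like growth factor binding protein gene, 57.6, and SERTAD3 56.4. HAND2 regions overlapped LARS2, DUOX1 with SHF, IGFBP4 and SERTAD3 among these places, and MEIS2 regions overlapped none of the 10.

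The 3 factors shared far more regions than chance placement gave. Of the 2311 MEIS2 regions, 86.4% (84.9 to 87.7%) overlapped a HAND2 region, against a mean of 2.30% for shuffled regions, and 45.6% (43.5 to 47.6%) overlapped a TCF4 peak, against 2.83%. Of TCF4 peaks, 41.5% (40.9 to 42.1%) overlapped a HAND2 region, against 2.51%. Moving each region by 25 to 100 kb, which keeps it in its neighbourhood, left overlaps of 8.75, 5.13 and 7.89%. At gene ends 89.4% of HAND2 regions overlapped a TCF4 peak, and 48.6% did so elsewhere. Conversely, 27.8% of TCF4 peaks at gene ends and 47.6% of those elsewhere overlapped HAND2. TCF4 occupied an end of 53.9% of all protein-coding genes, so its density at gene ends may raise the first of these shares. Shuffling did not keep regions at gene ends and gives no base rate for them. By gene, 3549 of 19970 protein-coding genes had both HAND2 and TCF4 at an end, where independent lists would share 2057. HAND2 and MEIS2 shared 153 against 36.1, and MEIS2 and TCF4 149 against 102 (two-sided Fisher's exact test, p = 1.10e-12). The MEIS2 overlaps depend on which replicate is used: MEIS2 replicate 2 alone gave 26.9% with HAND2 and 9.01% with TCF4, and replicate 1 alone 76.5 and 66.6%. The genes that MEIS2 shared with HAND2 numbered 1513 with replicate 1 alone (440 for independent lists) and 228 with replicate 2 alone (83.1), and those shared with TCF4 2176 (1242) and 264 (235). All 5 lists were treated as called against the same IgG control, so part of the excess may come from that shared control.

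Regions with all 3 factors numbered 1019, against a mean of 35.6 with MEIS2 shuffled and a highest value of 51. With MEIS2 replicate 1 alone they numbered 4997. Each is a merged span of regions linked by overlaps, so not every pair of factors in it need overlap. The folds given are each library's highest within the span. The region with the best worst rank across the 5 libraries lay on chromosome 11 from 15841011 to 15844082, 122366 bp from SOX6, with folds of 34.0 and 50.04 for HAND2, 18.3 and 25.5 for MEIS2 and 65.5 for TCF4. A pair of adjacent regions on chromosome 17 followed among the 10 highest: 40303122 to 40308253 at CDC6, with 27.1, 29.97, 15.4, 21.4 and 39.3 in the same order, and 40308768 to 40315063 at RARA, with 30.2, 26.7, 15.9, 13.8 and 20.1. In the span at CDC6, the MEIS2 region that held the 21.4 (40303122 to 40304614) overlapped no TCF4 peak. Within CLPB, a mitochondrial chaperone gene, the region on chromosome 11 from 72355717 to 72361041 had 99.4, 84.2, 43.3, 12.5 and 79.4. The others lay in WDR25 and nearest to NDRG4, PIK3R1, FERMT2, TTC8 and SULF2, at 3311 bp (SULF2) to 252853 bp (PIK3R1) from the gene. All 3 factors were present at an end of 132 genes (1464 with MEIS2 replicate 1 alone and 182 with replicate 2 alone), and none at 8917.

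Exclusive regions, which overlapped no peak of any library of the other factors, made up 31.9% of HAND2 regions (7423), 4.59% of MEIS2 regions (106) and 43.2% of TCF4 peaks (13262). For MEIS2 the share was 64.3% (8918) without MEIS2 replicate 1, 6.74% (647) without MEIS2 replicate 2 and 11.6% (269) without HAND2 replicate 1. HAND2 had 13093 exclusive regions (39.1%) without its replicate 1 and 12354 (40.6%) without its replicate 2. The strongest for HAND2 lay in SLC39A11 on chromosome 17 (72773749 to 72777052), with folds of 96.7 and 91.7, then 89670 bp from SHOX2, at 61.1 and 64.3, and in DPP6, CREB3L2 and BCAR3. For MEIS2 they lay 110950 bp from SNX10 (12.4 and 23.8), 61200 bp from NUDT12, 242545 bp from ZNF703, in TMC3 (10.7 and 31.1) and 404510 bp from KLF4. Those of TCF4 included the region at MAPKBP1 and JMJD7 above, PRR5 at 54.7, 2050 bp from AGRN at 47.4, and CIMAP1D at 45.0.

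TCF4 lay at gene ends most often of the 3. The summit was within 1 kb of an end of a protein-coding gene for 31.0% of TCF4 peaks (30.5 to 31.5%), 12.2% of HAND2 regions (11.8 to 12.7%) and 5.19% of MEIS2 regions (4.32 to 6.18%), against 3.33, 2.93 and 2.68% after shuffling. A further 44.9, 53.2 and 49.8% lay inside genes away from their ends. TCF4 occupied an end of 10768 genes, HAND2 3815 and MEIS2 189, but MEIS2 replicate 1 alone occupied 2303 and replicate 2 alone 435. The HAND2 replicates differed by less than they differed from TCF4, at 10.9 and 13.9%, but the MEIS2 replicates stood at 18.8 and 2.34%, on either side of HAND2, so no order of MEIS2 and HAND2 holds across replicates.

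**Figure D3:**
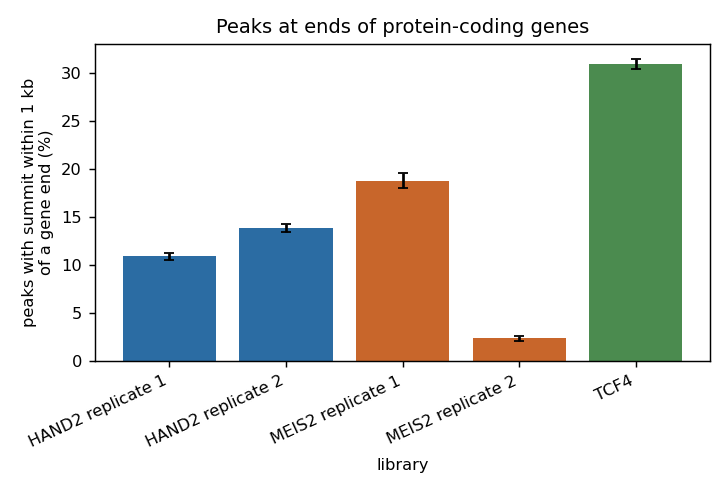
Bars give the percentage of each library's peaks whose summit lies within 1 kb of either end of a protein-coding gene, with 95% exact binomial intervals that cover counting error only. TCF4 stands at 31.0%, the HAND2 replicates at 10.9 and 13.9%, and the MEIS2 replicates at 18.8 and 2.34%.

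HAND2 was found at gene ends of the regulators and products of the adrenergic (sympathetic neuron-like) state more often than at other genes. Of 25 adrenergic regulators, 19 had a HAND2 region at an end (76.0% against 19.0% of other genes, Fisher's exact test, adjusted p = 1.48e-08), led by TLX2 at 10.8-fold, HAND1 at 10.1, PHOX2A at 9.44 and TBX2 at 6.31 (lower of the replicates). The 19 include MYCN (1.89), where the control signal is high. Without peaks of 30 or more IgG fragments the odds ratio was 10.9 against 13.5 (exact test, adjusted p = 1.75e-07). Neuronal differentiation genes followed with 16 of 28 (exact test, adjusted p = 6.88e-05), among them the receptor genes GFRA3 at 15.4 and CNTFR at 12.6, although the replicate 1 peak reaching the end of CNTFR had 4.75. The list of bHLH and ID factors had 13 of 32 (exact test, adjusted p = 0.0154), with HES1 at 10.46 and BHLHE40 at 10.2, and catecholamine synthesis and storage 9 of 20 (adjusted p = 0.019), with SLC6A2 at 77.1, CYB561 at 13.9 and DBH, which makes noradrenaline, at 13.3. Mesenchymal state genes, markers of the alternative state of neuroblastoma cells, had 11 of 30 (exact test, adjusted p = 0.0464), with SNAI2 at 8.66 and ID1 at 8.15. That last call was lost without either HAND2 replicate (exact test, adjusted p = 0.195 without replicate 2 and 0.124 without replicate 1), at odds ratios of 1.93 and 1.99 against 2.46. The bHLH and ID call was lost likewise (exact test, adjusted p = 0.0611 and 0.107), at 2.32 and 2.02 against 2.9, and the catecholamine call without replicate 1 (0.096), at 2.6 against 3.47. Without replicate 1 the odds ratio fell from 13.5 to 8.25 for adrenergic regulators and from 5.67 to 3.47 for neuronal genes, and both calls held (exact test, adjusted p = 9.89e-06 and 0.00499). At a −log10 q of 5 or more the odds ratio of adrenergic regulators was 8.18 (exact test, adjusted p = 6.54e-06). With the 5000 top peaks per library the mesenchymal and neuronal calls were lost (exact test, adjusted p = 0.0824 and 0.078), with odds ratios of 5.25 and 5.67, against 2.46 and 5.67 with all peaks. The adrenergic, bHLH and ID, and catecholamine calls held there (exact test, adjusted p = 0.0108, 0.00088 and 0.0341). Their odds ratios were 9.03, 10.99 and 8.35, against 13.5, 2.9 and 3.47. The mesenchymal call was also lost with a 500 bp window (exact test, adjusted p = 0.058, odds ratio 2.47) and without peaks of 30 or more IgG fragments (0.0823, odds ratio 2.62). Olfactory receptor genes were lower, with 3 of 390 (exact test, adjusted p = 3.08e-30). The remaining lists did not pass: cell cycle 12 of 34 (adjusted p of 0.0566 by the exact test and 0.0459 by permutation against matched lists; CDC6 at 27.1, with 14.1 for the replicate 2 peak that reached its end), ribosomal protein 18 of 72 (RPL38 at 9.85), TALE homeobox 5 of 18 (MEIS1 at 6.15), neural crest and Schwann cell precursor 5 of 20 (MSX2 at 19.2, with 4.93 for the replicate 1 peak that reached its end), HOX 5 of 39 (HOXC4, HOXC5 and HOXC6 on a shared region at 5.91), liver 2 of 20 (TAT at 4.18) and blood cell 1 of 21 (CD79A at 3.89).

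MEIS2 regions in both replicates lay at an end of 4 of the 25 adrenergic regulators: MEIS1 at 5.11-fold, ISL1 at 4.96, HAND2 at 3.74 and MEIS2 at 2.97 (16.0% against 0.928%, Fisher's exact test, adjusted p = 0.000547). Mesenchymal state genes had 4 of 30, SNAI2, VIM, ID1 and MAML2 (exact test, adjusted p = 0.000979), and bHLH and ID factors 4 of 32, ID2, ID1, ID3 and HAND2 (adjusted p = 0.00111). TALE homeobox genes had 2 of 18, MEIS1 and MEIS2 (exact test, adjusted p = 0.0301, and 0.0825 against matched random lists). The region at ID1 reached the gene end through a replicate 1 peak alone, and that at SCG2 through a replicate 2 peak alone. Other lists had at most 2 members and did not pass: cell cycle 2 of 34 (CDC6 and TOP2A), and 1 each of catecholamine (SCG2), neuronal (STMN2), neural crest (SNAI2) and ribosomal protein genes (RPL35A). HOX, liver, blood cell and olfactory receptor genes had 0 (for the last, permutation test against matched lists, adjusted p = 0.0399). MEIS2 replicate 1 alone put a peak at 16 of 25 adrenergic regulators (exact test, adjusted p = 6.67e-09), 7 of 30 mesenchymal genes (0.129) and 13 of 32 bHLH and ID factors (0.00012). Replicate 2 alone gave 4 of 25 (exact test, adjusted p = 0.00847), 5 of 30 (0.00243) and 4 of 32 (0.0143). The odds ratios of these 3 lists were 20.3, 16.4 and 15.2 with both replicates, 13.7, 2.34 and 5.27 with replicate 1 alone and 8.62, 9.07 and 6.47 with replicate 2 alone. At a −log10 q of 5 or more they were 13.15, 10.8 and 10.08 (exact test, adjusted p = 0.0358, 0.0413 and 0.044). The TALE call was lost with either replicate alone (0.085 and 0.112, at odds ratios of 2.96 and 5.64 against 13.2) and at a −log10 q of 5 or more (0.202, at 8.83). With the 5000 top peaks per library all 4 calls above other genes were lost, with 0 members left of the adrenergic, bHLH and TALE lists and an adjusted p of 0.167 for mesenchymal genes (exact test, odds ratio 15.96 against 16.4 with all peaks). Only 2.58% of the 891 MEIS2 regions of that set lay at a gene end, so a count of 0 gives no direction. Replicate 1 alone added calls above other genes for neuronal differentiation (12 of 28, 0.00012), ribosomal protein (21 of 72, 0.000159), cell cycle (10 of 34, 0.0102) and catecholamine genes (6 of 20, 0.0423), and one below for olfactory receptor genes (0 of 390, 2.68e-20). Replicate 2 alone added neuronal differentiation above (3 of 28, 0.0487) and olfactory receptor genes below (1 of 390, 0.0133).

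TCF4 was at the ends of cell cycle and DNA replication genes for 31 of 34 (91.2% against 53.9% of other genes, Fisher's exact test, adjusted p = 5.50e-05), with CCND1 at 31.9-fold, E2F2 at 20.5 and ODC1 at 20.2. Ribosomal protein genes had 54 of 72 (exact test, adjusted p = 0.00138), with RPL10 at 33.3 and RPL18 at 21.1, and adrenergic regulators 21 of 25 (adjusted p = 0.00781), with TLX2 at 50.5, PBX3 at 48.5 and GATA2 at 27.6. Lower than other genes were HOX with 11 of 39 (exact test, adjusted p = 0.0072, and 0.0932 against matched lists), liver with 4 of 20 (0.00894, APOC3 at 15.6), blood cell with 5 of 21 (0.019, KLF1 at 13.0) and olfactory receptor with 2 of 390 (2.77e-127). No call was made for neuronal differentiation (19 of 28, CNTFR at 26.2), catecholamine (14 of 20, CYB561 at 40.8), bHLH and ID factors (20 of 32, HES1 at 38.8; permutation test against matched lists, adjusted p = 0.0182), TALE homeobox (12 of 18, PBX3), mesenchymal (14 of 30, SNAI2 at 29.0) and neural crest genes (7 of 20, SNAI2). With peaks of 30 or more IgG fragments left out, the odds ratio of cell cycle genes fell from 8.85 to 2.48 (exact test, adjusted p = 0.0413). The adrenergic, HOX, liver and blood cell calls then ended (exact test, adjusted p = 0.0948, 0.103, 0.0889 and 0.282), with odds ratios of 2.3, 0.459, 0.27 and 0.478, against 4.49, 0.335, 0.213 and 0.267 with all peaks. Among the 5000 top TCF4 peaks the ribosomal protein, HOX, liver and blood cell calls were lost (exact test, adjusted p = 0.557, 0.966, 0.831 and 0.359), with odds ratios of 0.55, 0.614, 0.388 and 0. The cell cycle and adrenergic calls held there (exact test, adjusted p = 0.00347 for both), at odds ratios of 4.04 and 4.93 against 8.85 and 4.49.

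**Figure D4:**
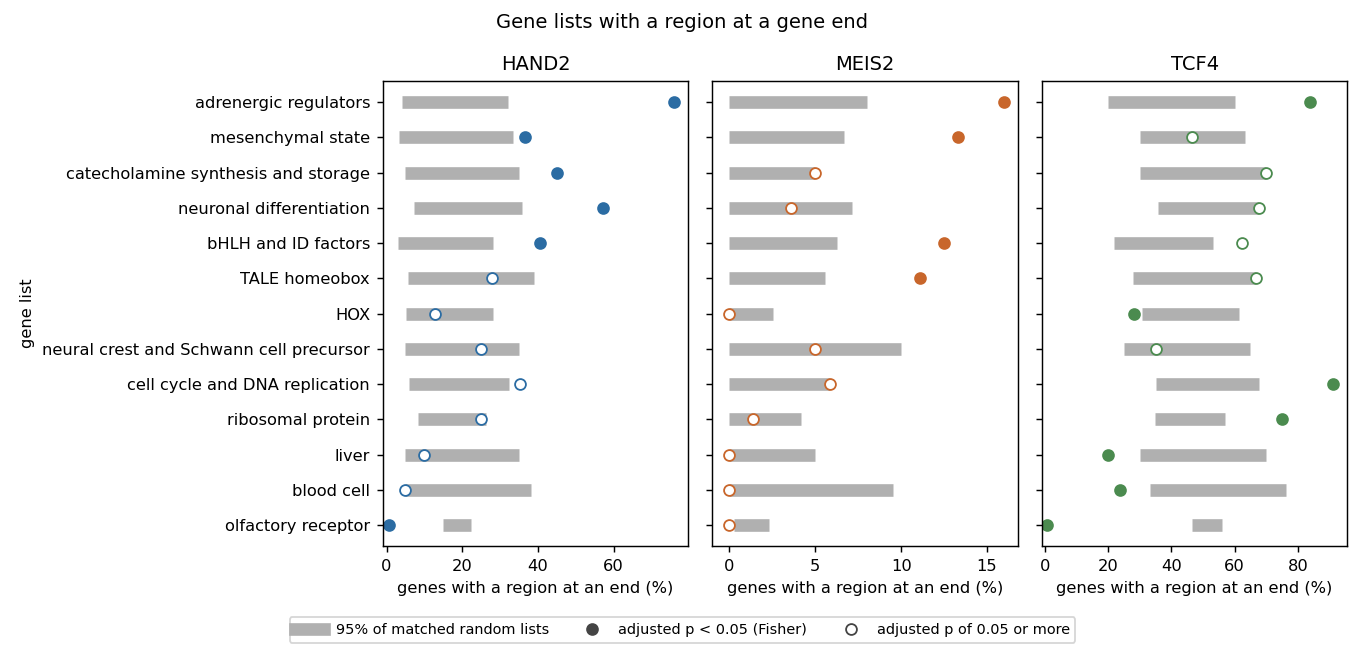
Points give the percentage of each list's genes with a region at an end for HAND2, MEIS2 and TCF4 (filled where Fisher's exact test passed after adjustment), and grey bars the central 95% of 10000 random lists matched on gene length and gene density. The horizontal scale differs between panels: the adrenergic regulators stand at 76.0% for HAND2, 16.0% for MEIS2 and 84.0% for TCF4.

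Within 50 kb of gene ends the adrenergic regulators held a mean of 5.92 HAND2 regions per gene (SD 5.17 over 25 genes), against 1.16 in matched random lists, 0.92 MEIS2 regions against 0.119 and 5.88 TCF4 peaks against 1.57 (permutation test, adjusted p = 0.000975 in each, from a p of 0.0002, the smallest that 10000 lists can give). KLF13 had 22 HAND2 regions and 20 TCF4 peaks, GATA2 15 and 17, and HAND2 had 6 MEIS2 regions. Catecholamine genes held 5.5 HAND2 regions against 1.57 (permutation test, adjusted p = 0.000975; SLC6A2 17, DDC 16), 0.6 MEIS2 regions against 0.11 (0.0039; SCG2 3) and 6.3 TCF4 peaks against 2.72 (0.0042; TH 19). For bHLH and ID factors the means were 3.13 HAND2, 0.438 MEIS2 and 4.72 TCF4 (permutation test, adjusted p = 0.000975, 0.0151 and 0.00173), and for cell cycle genes 3.06, 0.353 and 5.24 (0.00836, 0.0371 and 0.00936). These MEIS2 means rest on few genes: 6 of 32 bHLH and ID factors (SD 1.19), with HAND2 and its 6 regions among them, and 5 of 34 cell cycle genes (SD 1.01). Higher for HAND2 were also neuronal differentiation (3.64 against 1.8, permutation test, adjusted p = 0.0156; CNTFR 15), neural crest (3.15 against 1.36, 0.016; ETS1 14) and ribosomal protein genes (2.11 against 1.48, 0.0498), and for TCF4 ribosomal protein genes (5.92 against 3.84, 0.00234; RPS2 27). Liver genes were lower for HAND2 (0.5 against 1.6, 0.023) and TCF4 (1.05 against 3.31, 0.0039), and olfactory receptor genes for all 3 (0.000975). Mesenchymal, TALE, HOX and blood cell genes passed for none of the 3 factors. The neural crest call was lost with windows of 20 and 100 kb (permutation test, adjusted p = 0.0583 and 0.0661), at ratios to matched lists of 2.05 and 1.87 against 2.31, and that of ribosomal protein genes for HAND2 likewise (0.713 and 0.167), at 1.1 and 1.28 against 1.43. At a −log10 q of 5 or more that HAND2 call (permutation test, adjusted p = 0.127) and the MEIS2 calls for bHLH and ID factors (0.141) and cell cycle genes (0.062) were lost, with ratios to matched lists of 1.36, 3.06 and 3.46 against 1.43, 4.27 and 3.35 with all peaks. With the 5000 top peaks those 3 calls were lost too (permutation test, adjusted p = 0.381, 0.697 and 0.191), at ratios of 1.47, 1.89 and 3.64. So were the HAND2 calls for neuronal, neural crest, cell cycle and liver genes (permutation test, adjusted p = 0.123, 0.123, 0.416 and 0.191), whose ratios went from 2.02, 2.31, 1.96 and 0.314 to 2.42, 3.03, 1.59 and 0. The MEIS2 call for adrenergic regulators (0.379) and the TCF4 calls for ribosomal protein and liver genes (0.241 and 0.379) were lost as well, at ratios of 2.94, 1.34 and 0.479 against 7.76, 1.54 and 0.317 with all peaks. Without MEIS2 replicate 1 the cell cycle call for MEIS2 was lost (permutation test, adjusted p = 0.404), mesenchymal genes were called above matched lists (0.000975) and HOX genes below (0.0026). Without MEIS2 replicate 2, neuronal differentiation (0.00634) and HOX genes (0.0103) were called above and liver genes below (0.0424). For adrenergic regulators the MEIS2 mean was 2.28 against 0.701 in matched lists without replicate 1 and 4.52 against 0.523 without replicate 2, ratios of 3.25 and 8.64 beside 7.76 with both. Without replicate 1 the ratio fell from 5.44 to 2.37 for catecholamine genes, from 4.27 to 2.23 for bHLH and ID factors and from 3.35 to 1.372 for cell cycle genes. Without replicate 2 these ratios were 4.3, 3.45 and 2.6. That of olfactory receptor genes was 0.175 with both, 0.267 without replicate 1 and 0.0749 without replicate 2.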

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

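The test of the signal near MYCN was set before its result was seen, and the comparisons of lists between factors were planned before the data were examined, except those over all regions, which were chosen after. Peaks within 500 kb of MYCN stood out for the control signal beneath them. The median number of IgG fragments at their summits was at least 47.5 times that of other peaks on chromosome 2 (in MEIS2 replicate 1). In MEIS2 replicate 2 it was 143.7 times, although its median near MYCN was the lowest, at 298.9. The other lists had 485.5 to 1292 there. The remaining chromosome 2 peaks of MEIS2 replicate 2 had a median of 2.08, against 7 to 17.7 in the other lists. The high stretch ran from about 15900001 to 16500000, where 100 kb bins had medians of 302 to 834.5 IgG fragments, against 8.68 over all peaks. Within 500 kb of MYCN the lists hold 114, 96, 70, 79 and 27 peaks (HAND2 replicates 1 and 2, MEIS2 replicates 1 and 2, TCF4), with median folds of 1.88 to 2.9, below the 4.86 to 6.31 on the rest of the chromosome. Amplified copies of this region, which SK-N-BE(2) is known to carry, are a candidate explanation. A ratio of 3 or more in every library was set beforehand, and the lowest was 47.5. All lists were treated as sharing the same IgG control, so their ratios are not independent checks. They measure no copies in the HAND2, MEIS2 or TCF4 libraries. Amplification in these cells was known, so the test could hardly fail and adds no separate support. No copy number was measured here. Whether any of these peaks marks binding beyond the copy number stays open, and no biological explanation was tested.

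Several lists differed between factors when each factor kept its 2311 regions of highest fold, given as an excess over the difference in matched random lists, with adjusted permutation p-values. These were all MEIS2 regions but only the strongest HAND2 regions and TCF4 peaks, so the comparison sets different strengths of signal side by side, and 5 of the 9 differences changed sign over all regions. Adrenergic regulators had no HAND2 region at an end, 16.0% had MEIS2 and 20% TCF4, giving HAND2 minus MEIS2 of -15.3 percentage points (permutation test, adjusted p = 0.00585) and HAND2 minus TCF4 of -18.9 (permutation test, adjusted p = 0.0026, from the smallest p that the random lists can give, 0.0002). Over all regions 76.0% had HAND2, 16.0% MEIS2 and 84.0% TCF4, and the excesses were 45.05 (permutation test, adjusted p = 0.00111) and 15.45 (0.225). For mesenchymal genes HAND2 minus MEIS2 was -12.8 (0.0026) and MEIS2 minus TCF4 11.2 (0.0208), and over all regions 7.18 (0.517) and 12.4 (0.316). Among bHLH and ID factors the values were -11.8 (0.00936) and 10.2 (0.0303), and over all regions 13.97 (0.13) and -13.45 (0.262). Catecholamine genes had HAND2 minus MEIS2 of 10.4 (0.0303), and 23.04 (0.0702) over all regions. No direction between factors is drawn for these 4 lists. Olfactory receptor genes had no region of any factor in this set, and their excess of 3.58 for HAND2 minus TCF4 (0.0026) and 2.97 for MEIS2 minus TCF4 (0.0303) comes from the TCF4 peaks at the matched genes. Over all regions these excesses were 32.7 and 49.3 (permutation test, adjusted p = 0.00111 for both).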

How the results depend on the processing

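The set limited to peaks under 30 IgG fragments, the regions moved by 25 to 100 kb, the replicate block and the differences between factors over all regions were chosen after seeing the data, and the other settings before. HAND2 and MEIS2 share replicate numbers, which the labels tie to no batch or day. The gene-end share of HAND2 libraries minus that of MEIS2 libraries was 1.8 points, with a standard error of 8.38 without a block and 9.73 with the replicate number as a block (-7.93 and 11.5 by number); exact permutation tests can go no lower than p = 0.333 and 0.5 there. The motif analysis with its alternatives and the 5′ ends of all transcripts were not run, nor lists matched on promoter GC. A reciprocal overlap of 50% gave 1265 MEIS2 regions, 63% of them with HAND2 and 26.0% with TCF4, 23.3% of TCF4 peaks with HAND2 and 279 regions of all 3 factors, and summits within 200 bp gave 1338, 67.9%, 30.7%, 26.1% and 376. With all peaks the MEIS2 shares were 86.4 and 45.6%. These rules admit fewer pairs by construction. With the 5000 top peaks per library there were 4068 HAND2 and 891 MEIS2 regions, 58.6% of the latter with HAND2 and 14.6% with TCF4, 32.5% of TCF4 peaks with HAND2, 126 regions of all 3, gene-end shares of 4.84% (HAND2) and 32.8% (TCF4), and 9 gene lists called at gene ends and 12 within 50 kb, against 17 and 21 of 39. In that smaller set 0 members of the adrenergic, bHLH and TALE lists had MEIS2 at an end. Only 2.58% of the 891 MEIS2 regions lay at a gene end there. Lists of this size would hold hardly any of them by chance, so a count of 0 gives no direction. The odds ratio of ribosomal protein genes for TCF4 was 0.55, and its cause was not tested. A −log10 q of 5 or more gave a TCF4 gene-end share of 32.4%. Gene-end windows of 500 bp gave 9.5% for HAND2 and 25.9% for TCF4, and 2.5 kb gave 18.1 and 38.8%, as wider windows must. Under 30 IgG fragments, the shares were 9.48 and 25.9%; the cause was not tested. Leaving out each replicate gave 26.9 to 93.8% of MEIS2 regions with HAND2, 43.0 to 52.9% of TCF4 peaks with HAND2, 1030 to 4997 regions of all 3 and a MEIS2 gene-end share of 2.34 to 18.8%. Observed over chance overlap with moved regions was 9.87 (MEIS2 with HAND2), 8.88 (MEIS2 with TCF4) and 5.26 (TCF4 with HAND2), against 37.5, 16.1 and 16.6 with shuffled ones. Of the list calls, 34 held and 4 were lost at the stricter q, and 33 held and 5 were lost under 30 IgG fragments. With the 5000 top peaks 18 held and 20 were lost, 4 of these with an odds ratio on the other side of 1. Those 4 were ribosomal protein genes for TCF4 and the adrenergic, bHLH and TALE lists for MEIS2, with their counts of 0. In all, 14 lists were called at gene ends and 22 within 50 kb without HAND2 replicate 1. Without HAND2 replicate 2 there were 16 and 21. Over all regions 5 differences between factors changed sign: adrenergic regulators to 45.05 points (HAND2 minus MEIS2) and 15.45 (HAND2 minus TCF4), mesenchymal genes to 7.18 and bHLH and ID factors to 13.97 (HAND2 minus MEIS2) and -13.45 (MEIS2 minus TCF4). The number of regions per factor differs between these settings by construction. The shallow MEIS2 libraries limit what can be called absent there.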

Other observations

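The HOX clusters differed from each other, in a comparison made after the values were seen. None of the 5 libraries had a peak summit within the HOXA cluster (11 genes, chromosome 7, 27092993 to 27200091) or the HOXB cluster (10 genes, chromosome 17, 48528526 to 48728750). The HOXC cluster (9 genes, chromosome 12, 53938831 to 54056030) held 9 HAND2 regions and 10 TCF4 peaks, and HOXD (9 genes, chromosome 2, 176087487 to 176190907) held 3 and 12. HAND2 lay at an end of HOXC4, HOXC5, HOXC6, HOXD10 and HOXD11, and TCF4 also at HOXC9, HOXC10, HOXD1, HOXD8, HOXD9 and HOXD12. MEIS2 replicate 1 had 4 peaks in each of HOXC and HOXD and replicate 2 had 0, so no MEIS2 region was called. No test was made, since genes of a cluster are not independent.

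Genes with the most regions within 50 kb were also listed after the values were seen, with no test between factors. For HAND2 these were GSE1 with 36 regions, ZMIZ1 with 35 and TCF20 with 34, against a median of 1 over all genes, and for TCF4 FLRT1 with 45, PLCH2 with 41 and MEGF6 with 40, against a median of 2. The lists overlapped in part, since GSE1 also had 39 TCF4 peaks and FLRT1 27 HAND2 regions. MEIS2 had most at CLPB, with 9 beside 30 HAND2 regions, followed by histone genes of chromosome 6 such as H2AC7 and H2BC5 with 7, where 91.8% of genes had none. The histone genes share windows and have near-identical copies, so their counts are uncertain.

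For the disagreement of the MEIS2 replicates, the tests of depth and of the antibody were chosen after the overlap was seen, and that of background before. Shallow sequencing as the whole cause is argued against by the strongest 1000 peaks of replicate 2, of which 37.8% (34.8 to 40.9%) overlapped replicate 1, although their pile-up scaled to replicate 1's depth would be 25.6, above the 10th percentile of 10. IgG-like background at open sites in replicate 1 stays open: overlap with HAND2 was 64.0% at peaks with 3 or fewer IgG fragments and 78.9% at those with more than 10, a ratio of 0.811 (0.777 to 0.844). Of replicate 1 peaks with 3 or fewer IgG fragments, 51.5% (48.8 to 54.1%) overlapped replicate 2, against 24.6% of all its peaks. Of replicate 2 peaks with 3 or fewer, 9.07% (8.51 to 9.66%) overlapped replicate 1, against 16.8% of all its peaks. Another antibody or tag in replicate 2 also cannot be told apart from a difference between replicates, since the word Flag and the low background (57.7% of its peaks at the lowest control level, against 9.5% in replicate 1) occur in the same single library. No biological explanation was tested.

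For the sharing of TCF4 peaks with HAND2, the test of IgG-like background was set before its result was seen and that of clustering after. Background at open sites would make the overlap rise with IgG signal. The overlap rose slightly, from 41.2% at TCF4 peaks with 9 or fewer IgG fragments to 43.9% at those with 22 or more. The ratio was 0.938 (0.904 to 0.973), a smaller rise than the one set beforehand as a sign of background. Position may hide a larger rise, since TCF4 peaks at gene ends overlapped HAND2 less (27.8% against 47.6% elsewhere). Leaving out peaks of 30 or more IgG fragments lowered the gene-end share of TCF4 peaks from 31.0 to 25.9%. The test therefore cannot decide on background. Moving the TCF4 peaks by 25 to 100 kb kept 0.19 of the overlap. This argues against clustering over such distances as the whole cause. Clustering within less than 25 kb was not tested. Open chromatin cut in every library and joint binding of both proteins were not tested here and stay open.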
